A study of Mus musculus with 5 samples.

How the data were processed

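Single-cell RNA of mouse blastoids was measured in 5 libraries, which per the labels were made with the 10x Next GEM 3' kit v3.1. According to the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 6.1.2 and analysed with Seurat 3.0. The annotation release behind the gene table is not given in the sources used here. The deposited matrices hold raw UMI counts, whole numbers for 32285 genes per barcode, without normalization by the authors. Each library comes with its barcodes and genes, and 32158 genes (99.6%) were found by identifier in the GENCODE vM21 annotation (GRCm38, the same assembly as mm10), which supplied chromosome, start, end and strand. Gene symbols were those of the deposited table. For 78 symbols held by more than 1 gene the identifier was used. Groups followed the library titles: hypoxia day 2 (n = 1), hypoxia day 3 (n = 2) and normoxia day 3 (n = 2). The growth protocol of all 5 libraries describes a post-culture at 20% oxygen, so hypoxia is known only from the titles and treatment labels, which give no oxygen level.

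The choices of cell filter, cluster settings, markers, gene lists, tests, thresholds and rule for named genes were made before the data were examined. Comparisons of day within each class, the counting of cluster 13 as EPI-like, the thinning of the interaction, the contrast of TE-like with PrE-like cells, the clustering without Y-linked genes and the leaving out of libraries from the class shares were added afterwards. Barcodes with at least 1000 genes and under 15% of UMIs from mitochondrial genes were kept, which removed 3922 and 322 of 18323 barcodes. Scrublet scores, run through scanpy, ranked the remaining barcodes of each library, and the top 0.8% per 1000 barcodes were removed as presumed doublets (476 in all). The kept cells numbered 1866 at day 2, 2465 and 3773 in hypoxia day-3 replicates 1 and 2, and 1686 and 3813 in normoxia replicates 1 and 2.

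Clustering used scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen across libraries after leaving out HIF targets, glycolysis, mitochondrial, ribosomal, S phase and G2 and M phase genes. The graph used 30 principal components and 15 neighbours, and Leiden clustering was run at resolution 1 on all libraries together without batch correction. Each cluster was named from marker lists of cell types, by the mean of its marker levels relative to the highest cluster. A lineage name was given where its score clearly exceeded that of the next lineage, at least 3 of its markers were detected and its top genes held no more markers of another type than of its own. Clusters are therefore described as like a cell type, and the names were not tested by any other method. Shares of cells carry 95% Clopper-Pearson intervals. These intervals cover counting error only. Shares were compared between oxygen groups by an exact two-sided permutation test.

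For expression, UMI counts were summed per library over all kept cells or over the cells of 1 class, where every library held at least 20 such cells. Genes were kept with edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CPM values are UMI counts relative to the TMM-scaled library sums. The oxygen comparisons used the 4 day-3 libraries. The day comparisons used all 5 libraries in 3 groups, and the lone day-2 library was assumed to vary like the others. Differences of the oxygen effect between classes were tested by an interaction term with the library as a block. The genes named were, in each direction, up to 8 with the largest change among those past the threshold whose library values did not overlap and whose mean reached 20 CPM in the higher group, up to 4 called members with the smallest p of each called list, and a fixed set (Vegfa, Slc2a1, Pgk1, Ldha, Bnip3, Pdk1, Egln3, Pou5f1, Nanog, Sox17, Gata6, Cdx2 and Krt8). Where fewer than 5 were called, the 5 with the smallest p were named. Ndufa4l2 came under this rule. T was named outside it, after its values had been seen, because few UMIs lay behind them. Genes such as Ldha, Pgk1 and Fabp5 have related genes or pseudogenes that share sequence, and how their reads were divided is not known.

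The 34 gene lists, written from general knowledge of the field, were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, on lists with at least 5 tested members. Some lists share genes, so the counts of different lists are not independent. Fry tests whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. At an adjusted p under 0.05 fry called DNA methylation genes in EPI-like cells (adjusted p = 0.0055 for oxygen and 0.0086 for day) and formative pluripotency genes in TE-like cells for oxygen (adjusted p = 0.038), and no list in the other 5 comparisons. With an estimated correlation camera called no list in any of the 8 comparisons.

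The procedure was tested on simulated data with the depths of these libraries, in which 100 genes each were changed by a factor of 2 or 4. Each gene was given the dispersion that the fitted trend sets at its level, the same in all groups. Recovered were 60 and 87 of them for oxygen in all cells, 71 and 86 in EPI-like, 37 and 87 in PrE-like and 73 and 94 in TE-like cells. For day the numbers were 48 and 77 in all cells, 57 and 78 in EPI-like, 34 and 83 in PrE-like and 66 and 88 in TE-like cells. For the interaction they were 50 and 78 (TE-like against EPI-like) and 36 and 65 (TE-like against PrE-like). Between 2 and 10 unchanged genes were called in each run. Because dispersion did not scatter between genes or differ between groups, these runs cannot show how the procedure does where it does. A simulated list raised by a factor of 1.5 was called by camera with the preset correlation in all 5 comparisons tried, and missed with an estimated correlation (adjusted p = 0.0669 to 0.323), and no unchanged list was called. The simulated genes were drawn independently of each other. This run therefore cannot show how often the preset correlation leads to false calls where the genes of a list vary together. The replicates of a group were checked for duplication and differed by far more than counting error (chi-square per degree of freedom of 18.3 for hypoxia and 41.8 for normoxia).

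Alternatives tried were DESeq2 size factors in edgeR, DESeq2 1.42.0 with its Wald test, no filter on low counts beyond 1 count, doublets kept, cells with at least 2000 genes and under 10% mitochondrial UMIs, sums thinned to the smallest library, a fit over all 5 libraries, a Leiden resolution of 0.5, each library clustered by itself, the left-out gene lists kept among the variable genes, Y-linked genes left out of them, the replicate number as a block, and each day-3 library left out in turn. Figures were drawn with matplotlib 3.10.9. No reads were reanalysed, since only processed files were used.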

Results

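Gene expression was measured in single cells of mouse blastoids, which are embryo-like structures grown from stem cells that resemble the blastocyst. The 5 deposited libraries were made with droplet-based 3' single-cell RNA sequencing. They fall into 3 groups by their titles: hypoxia at day 2 (1 library), hypoxia at day 3 (2 libraries) and normoxia at day 3 (2 libraries). Normoxia day-3 replicate 2 is called day 3 in its title but day 4 in 1 characteristic, and the title was followed. The oxygen level of the hypoxia cultures is not given in the labels. The libraries held 59017162 unique molecular identifiers (UMIs) at day 2, 61464312 and 67764787 in hypoxia day-3 replicates 1 and 2, and 73397908 and 59125827 in normoxia replicates 1 and 2. Of 18323 barcodes, 13603 cells were kept. The median UMIs per kept cell were 22389 at day 2, 16955 and 11895 in the hypoxia day-3 replicates, 28390 in normoxia replicate 1 and 5889 in normoxia replicate 2. In normoxia replicate 2, 2520 of 6677 barcodes had under 1000 genes. Apart from those of camera, the p-values below measure only the spread between these libraries. That spread may be technical, since the labels do not say what a replicate repeats. Camera compares the genes of a list with other genes, and with a preset correlation its p-values rest largely on the number of genes.

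Cells resembling the 3 lineages of the blastocyst were found in every library. Epiblast-like (EPI-like) cells, which carry markers of the embryo proper such as Pou5f1, filled cluster 2 (697 of its 730 cells from day 2), cluster 7 and cluster 8. Primitive endoderm-like (PrE-like) cells, marked by Gata6 and Sox17, filled cluster 10, mostly from day 2, and cluster 14, mostly from day 3. Trophectoderm-like (TE-like) cells, marked by keratins and by Cdx2 and Eomes, filled clusters 0, 1, 3, 4, 5, 6, 9, 11, 12, 17, 18 and 19. Cluster 1 took 855 of its 937 cells, and cluster 17 took 925 of its 1017 cells, from the shallow normoxia replicate 2, as did all cells of clusters 18 and 19. A 2-cell-like cluster (cluster 15), with Zscan4-type markers, held 28 cells. Clusters 13 and 16 were left unnamed. Clusters that share top genes with cluster 13 were named EPI-like in the other 4 clusterings of all libraries together and in 4 of the 5 libraries clustered by themselves, so the EPI-like cells of those alternatives include them.

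The question of the first comparison was whether oxygen went with a different make-up of the blastoids. EPI-like cells were 39.5% of the kept cells at day 2 (95% Clopper-Pearson interval 37.3 to 41.8). Their shares were 42.7% (40.7 to 44.7) and 28.0% (26.6 to 29.5) in the hypoxia day-3 replicates, against 39.9% (37.6 to 42.3) and 5.98% (5.25 to 6.78) under normoxia. PrE-like cells were 8.74% (7.49 to 10.1) at day 2. They were 4.54% (3.76 to 5.44) and 12.9% (11.9 to 14.0) in hypoxia at day 3, against 3.20% (2.42 to 4.16) and 6.16% (5.42 to 6.97) in normoxia. TE-like cells were 47.2% (44.9 to 49.5) at day 2, 49.5% (47.5 to 51.5) and 57.2% (55.6 to 58.8) in hypoxia at day 3, and 49.3% (46.9 to 51.7) and 86.8% (85.7 to 87.9) in normoxia.

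None of these shares separated the oxygen groups by more than the spread between replicates. At day 3 the EPI-like share was 35.4% ± 10.3 under hypoxia and 22.9% ± 24.0 under normoxia (SD, n = 2 each; exact two-sided permutation p = 0.667). For PrE-like cells the means were 8.74% ± 5.93 and 4.68% ± 2.09 (exact permutation p = 0.667), and for TE-like cells 53.3% ± 5.43 and 68.0% ± 26.5 (exact permutation p = 1.0). The smallest p that 2 libraries against 2 can give is 0.333. Hypoxia minus normoxia was 12.4 percentage points for EPI-like and -14.7 for TE-like cells. Without normoxia replicate 2 the differences were -4.56 and 4.04, and without normoxia replicate 1 they were 29.4 and -33.5. Without hypoxia replicate 1 the PrE-like difference moved from 4.06 to 8.25, and without hypoxia replicate 2 to -0.139.

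**Figure D1:**
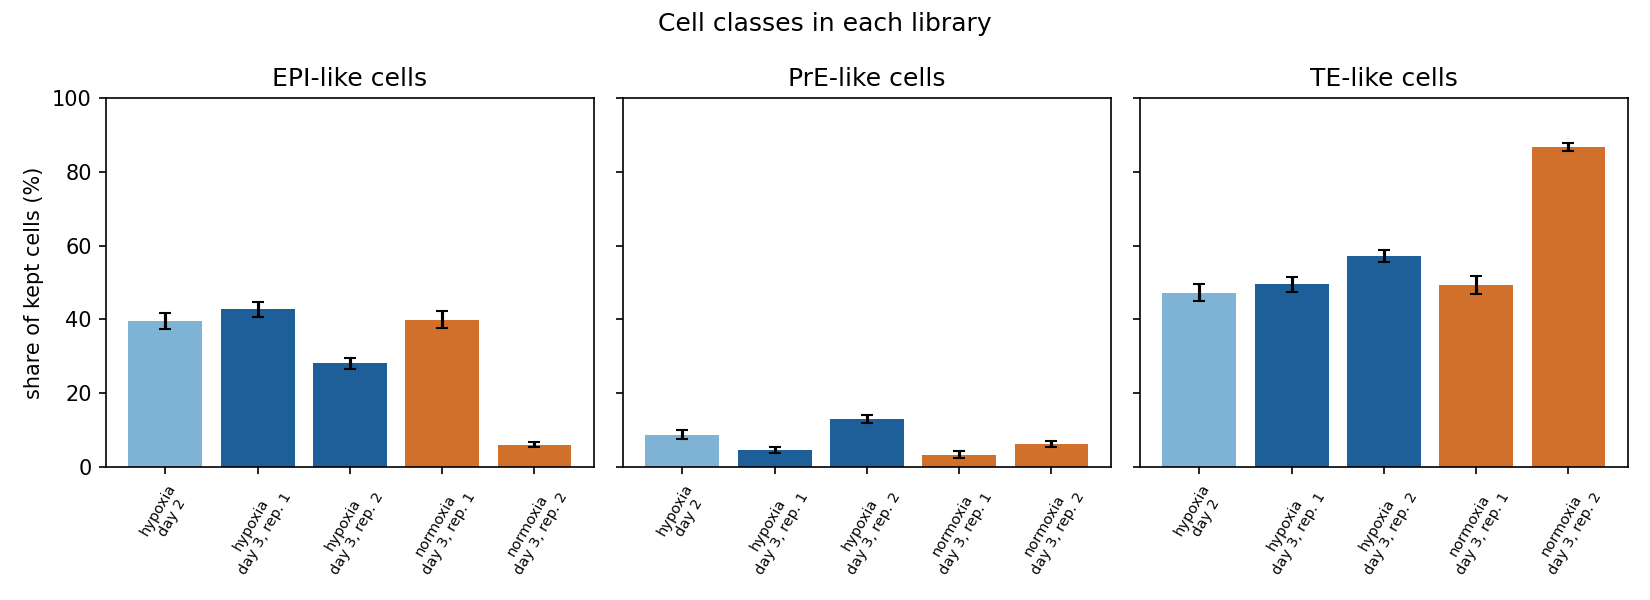
Share of kept cells (percent, y axis from 0) in each class for each of the 5 libraries, with 95% Clopper-Pearson intervals as error bars, which cover counting error only. The EPI-like share of normoxia replicate 2 (5.98%) lies below those of the other 4 libraries (28.0% to 42.7%). It was 6.43% to 10.2% under 4 alternatives, and 12.0% with each library clustered by itself, where 202 of its 457 cells named EPI-like formed a cluster with collagen genes and 0 EPI markers among its top 10 genes.

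Next, gene expression was compared between hypoxia and normoxia at day 3. Over all cells, hypoxia went with more RNA of Igfbp2, which encodes a binding protein of insulin-like growth factors, and of Slc16a3, which encodes a lactate exporter. Igfbp2 (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474, plus strand, mm10) had a CPM value (UMI counts scaled to a common library size) of 97.3 ± 6.38 under hypoxia and 10.96 ± 0.0767 under normoxia (SD, n = 2). Slc16a3 (ENSMUSG00000025161, chromosome 11, 120948480 to 120960868, plus strand) had 153 ± 37.2 and 19.7 ± 1.88 CPM. These 2 of 15350 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with log2 fold changes of 3.15 (SE 0.11, adjusted p = 0.00228) and 2.96 (SE 0.20, adjusted p = 0.0455), and 1536 genes had an unadjusted p under 0.05. Pfkp, a glycolytic enzyme, came next at 1.29 (edgeR adjusted p = 0.0548), and Krt8, a trophectoderm keratin, was at -0.68 (adjusted p = 0.15). Of 36 targets of the hypoxia-inducible factor (HIF) 1 rose (23 adjusted over the list alone), and of 16 glycolytic enzymes none over all genes and 13 adjusted over the list alone. Limma's camera test called 19 of 34 gene lists with its preset correlation, 13 higher and 6 lower, each at an adjusted p of 0.530 to 0.610 with an estimated correlation. The sums mix cell classes in shares that differed between libraries, and normoxia replicate 2 was mostly TE-like. The count was 17 without hypoxia replicate 1, 267 without normoxia replicate 1 and 45 without normoxia replicate 2, and DESeq2 called 253 genes.

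In EPI-like cells, genes of the hypoxia response and of glycolysis were higher under hypoxia. Of 33 measured HIF targets, 17 rose and none fell over all genes tested (23 rose adjusted over the list alone). Among them Slc16a3 went from 0.543 ± 0.238 to 42.8 ± 13.8 CPM (SD, n = 2; log2 fold change 5.999, SE 0.38, edgeR adjusted p = 0.00021). Bnip3, a mitophagy receptor (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519, minus strand), went from 6.47 ± 1.21 to 113 ± 33.4 CPM (4.02, SE 0.25, edgeR adjusted p = 0.00021). Of 16 glycolytic enzymes, 12 rose (13 rose and 1 fell adjusted over the list alone). Ldha, which makes lactate from pyruvate, went from 75.4 ± 20.6 to 893 ± 351 CPM (3.61, SE 0.29, edgeR adjusted p = 0.000473), and Pgk1 from 86.0 ± 6.04 to 652 ± 195 CPM (2.91, SE 0.20, edgeR adjusted p = 0.000262). The camera adjusted p was 0.441 with an estimated correlation for both lists.

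Other EPI-like genes that rose included Igfbp2, from 26.2 ± 1.63 to 441 ± 168 CPM (SD, n = 2; log2 fold change 4.09, SE 0.26, edgeR adjusted p = 0.00021), and the glucose transporter Slc2a1, from 31.3 ± 2.88 to 223 ± 52.0 CPM (2.81, SE 0.18, edgeR adjusted p = 0.00021). Vegfa, a growth factor for blood vessels, rose by 1.89 (SE 0.26, edgeR adjusted p = 0.0123). Of 14 BMP and TGF-beta targets, 5 rose (6 adjusted over the list alone), among them Id1 (0.90), Smad7 (0.92) and Msx2 (1.64). Of 7 genes of the mesoderm and primitive streak list, only Lefty2, an inhibitor of Nodal signalling, rose over all genes tested (1.70, 2 genes adjusted over the list alone). Of 12 nutrient transporters, 3 rose (5 adjusted over the list alone), in a list that shares Slc2a1, Slc2a3 and Slc16a3 with the HIF targets. The camera adjusted p of each of these 3 lists was 0.441 with an estimated correlation. Ndufa4l2, a HIF target, had 30.1 ± 19.6 CPM under hypoxia and 0.107 ± 0.151 under normoxia, the latter from 3 UMIs.

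Genes that fell in EPI-like cells numbered 32, but 1 with each library clustered by itself, 3 without normoxia replicate 1, 10 with doublets kept and 11 at the lower clustering resolution. They included Mep1b, a metalloprotease gene (-2.35, SE 0.39, edgeR adjusted p = 0.0324), Lpl, the lipoprotein lipase (-1.60), Rgcc (-1.29) and Pdcd4 (-1.17). Of 13 transcripts of the mitochondrial genome, only mt-Atp8 fell over all genes tested (-0.64), and 7 fell adjusted over the list alone (adjusted p = 0.441 with an estimated correlation). The mt-Atp8 gene overlaps mt-Atp6, so its count is uncertain. The median share of UMIs from mitochondrial genes per EPI-like cell was 6.08% and 5.46% under hypoxia and 7.36% and 6.95% under normoxia. The pluripotency genes Pou5f1 (0.21, edgeR adjusted p = 0.395; 821 ± 1.13 against 710 ± 43.0 CPM) and Nanog (0.19, edgeR adjusted p = 0.556) did not pass the test.

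In all, 79 genes rose and 32 fell of 12243 tested in EPI-like cells, all with both hypoxia libraries on 1 side of both normoxia libraries, a separation that chance alone gives with a probability of 0.333. At an unadjusted p under 0.05 there were 1916 genes. Camera called 15 of 32 lists, 11 higher and 4 lower. Besides those above, cholesterol synthesis, the integrated stress response, the endoplasmic reticulum stress response, ribosomal proteins, genes of G2 and M phase and genes of the polar trophectoderm were called higher, and p53 targets, nuclear subunits of oxidative phosphorylation and lysosome and autophagy genes lower. None of their members was called over all genes tested (4, 0, 0, 0, 0 and 2 higher and 6, 0 and 2 lower adjusted over the list alone). Their camera adjusted p lay between 0.441 and 0.741 with an estimated correlation. Most hypoxia cells, and 118 of the 228 cells of normoxia replicate 2, lay in cluster 7, whereas 589 of the 673 cells of normoxia replicate 1 lay in cluster 8. The count was 1509 (742 lower) without hypoxia replicate 1, 294 (148 lower) without hypoxia replicate 2, 44 (9 lists) without normoxia replicate 1, 237 (108 lower) without normoxia replicate 2, and 34 with each library clustered by itself, where the cluster with collagen genes was counted as EPI-like.

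In PrE-like cells the genes that rose under hypoxia were again mostly HIF targets and glycolytic enzymes. Of 31 HIF targets 6 rose (23 adjusted over the list alone), and of 15 glycolytic enzymes 6 rose (12 adjusted over the list alone). Bnip3 rose by 4.31 (SE 0.38), Slc2a1 by 2.37 (SE 0.24) and Ldha by 1.87 (SE 0.20), each at an edgeR adjusted p of 0.0141. Slc16a3 rose from 2.72 ± 0.153 to 78.6 ± 46.8 CPM (SD, n = 2; log2 fold change 4.86, SE 0.53, edgeR adjusted p = 0.0141). Klhl2, an adaptor of a ubiquitin ligase, rose by 2.12 (SE 0.24), and Egln1, an oxygen-sensing hydroxylase that marks HIF for degradation, by 2.05 (SE 0.27, edgeR adjusted p = 0.0309). Of 12 nutrient transporters 2 rose (3 adjusted over the list alone), namely Slc2a1 and Slc16a3, which are also HIF targets. Vegfa was at 1.07 (edgeR adjusted p = 0.291), and the lineage genes Sox17 (0.59, adjusted p = 0.439) and Gata6 (0.03) did not pass the test.

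The test called 13 of 9316 genes in PrE-like cells, all higher, with 585 at an unadjusted p under 0.05. Camera called 17 of 30 lists, 11 higher and 6 lower, at adjusted p values of 0.279 to 0.458 with an estimated correlation. Those without a member called over all genes were, on the higher side, the PrE markers (5 of 15 adjusted over the list alone), BMP and TGF-beta targets (4 of 11), the integrated stress response (3 of 18), parietal endoderm genes (2 of 15), visceral endoderm genes (1 of 6), and, with none, cholesterol synthesis, the endoplasmic reticulum stress response and the genes induced by cell dissociation. On the lower side were p53 targets (1 of 18 adjusted over the list alone) and, with none, oxidative phosphorylation, mitochondrial transcripts, S phase, trophectoderm markers and lysosome genes. The smallest class sum held 54 cells and 1562780 UMIs. Without either normoxia library the count was 0 by edgeR, and without hypoxia replicate 1 it was 193.

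In TE-like cells, HIF targets and glycolytic enzymes also rose under hypoxia, 20 of 36 (27 adjusted over the list alone) and 12 of 16 (14 adjusted over the list alone). Slc16a3 rose from 24.3 ± 1.30 to 189 ± 32.2 CPM (SD, n = 2; log2 fold change 2.96, SE 0.13, edgeR adjusted p = 9.12e-07). Ankrd37, a HIF target (ENSMUSG00000050914, chromosome 8, 45996902 to 46005707, minus strand), rose by 3.03 (SE 0.26, edgeR adjusted p = 8.73e-05). Pdk1, a pyruvate dehydrogenase kinase, rose by 2.58 (SE 0.21), Bnip3 by 2.39 (SE 0.19) and Ldha by 1.72 (SE 0.14), each at an edgeR adjusted p of 7.8e-05. Slc2a1 rose by 0.54 (SE 0.13, edgeR adjusted p = 0.0485), while Vegfa was at 0.32 (adjusted p = 0.288). The camera adjusted p was 0.518 with an estimated correlation for both lists.

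Some genes of the polar trophectoderm and of FGF-ERK feedback rose as well in TE-like cells. Of 18 polar genes 5 rose (10 rose and 1 fell adjusted over the list alone), among them Bmp4 (1.10, SE 0.13, edgeR adjusted p = 0.0013), Sox2 (0.77) and Ddah1 (0.61). Of 12 FGF-ERK genes 4 rose (6 adjusted over the list alone), among them the early response gene Egr1 (1.60, SE 0.19, edgeR adjusted p = 0.00119) and the feedback inhibitors Spry4 (0.99) and Spred1 (0.77). Of 16 formative pluripotency genes 2 rose, including Pou3f1 at 0.92 (5 rose and 1 fell adjusted over the list alone). The adjusted p of these 3 lists was 0.518 with an estimated correlation. Fos rose by 1.86 (SE 0.31, edgeR adjusted p = 0.00943), and like Egr1 it also belongs to the list of genes induced by cell dissociation. Of that list, 3 of 19 rose and it was not called by camera (adjusted p = 0.11).

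Other TE-like genes fell. Plac1 (ENSMUSG00000061082, chromosome X, 53069995 to 53240111, minus strand) fell by 1.45 (SE 0.20, edgeR adjusted p = 0.00275), and Ascl2, a transcription factor of the ectoplacental cone, by 1.16 (SE 0.13, edgeR adjusted p = 0.000819). Cdkn1c, an imprinted inhibitor of the cell cycle, went from 715 ± 77.0 to 350 ± 6.24 CPM (-1.03, SE 0.12, edgeR adjusted p = 0.000869). Of 19 imprinted genes 2 fell (5 adjusted over the list alone). Of 18 lysosome and autophagy genes 4 fell (10 adjusted over the list alone), among them Gpnmb (-0.88), Grn (-0.61), Psap (-0.59) and Gba (-0.57). Of 19 p53 targets only Mdm2 fell (-0.50, 4 adjusted over the list alone). The adjusted p of these 3 lists was 0.518 with an estimated correlation. Of 14 trophoblast differentiation genes 3 rose and 1 fell (5 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.561). The metal-binding genes Mt1 (-1.10) and Mt2 (-1.29) and the keratin Krt8 (-0.56, SE 0.13, edgeR adjusted p = 0.045) fell too. Of 20 core trophectoderm markers 2 rose and 3 fell, and the list was not called.

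The test called 317 of 13948 genes in TE-like cells, 197 higher and 120 lower, with 2458 at an unadjusted p under 0.05. Camera called 11 of 32 lists, 7 higher and 4 lower. Those not yet given were nutrient transporters (3 of 12 rose, 4 rose and 1 fell adjusted over the list alone, adjusted p = 0.544 with an estimated correlation), G2 and M phase genes (2 of 22 rose, 8 adjusted over the list alone, adjusted p = 0.583 with an estimated correlation) and oxidative phosphorylation (1 of 48 fell, 2 adjusted over the list alone, adjusted p = 0.789 with an estimated correlation). The TE-like cells of the 2 oxygen groups lay partly in different clusters. Cluster 6 held 375 of 1220 and 801 of 2157 in the hypoxia replicates but 128 of 831 and 182 of 3310 under normoxia, and cluster 11 held 230 and 186 of them under hypoxia against 393 and 394 under normoxia. TE-like cells of normoxia replicate 2 lay mostly in clusters 1 and 17 and had a median of 5139.5 UMIs. They held more RNA of Pou5f1 and Gata6, marker genes of other classes, than those of the other 3 libraries. Pou5f1 was at 15.9 CPM against 4.18 to 4.50, and Gata6 at 4.59 against 0.886 to 1.68. Where this RNA came from was not tested. Without hypoxia replicate 2 the count was 126, without normoxia replicate 1 it was 1103 (19 lists) and without normoxia replicate 2 it was 1619 (18 lists).

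**Figure D2:**
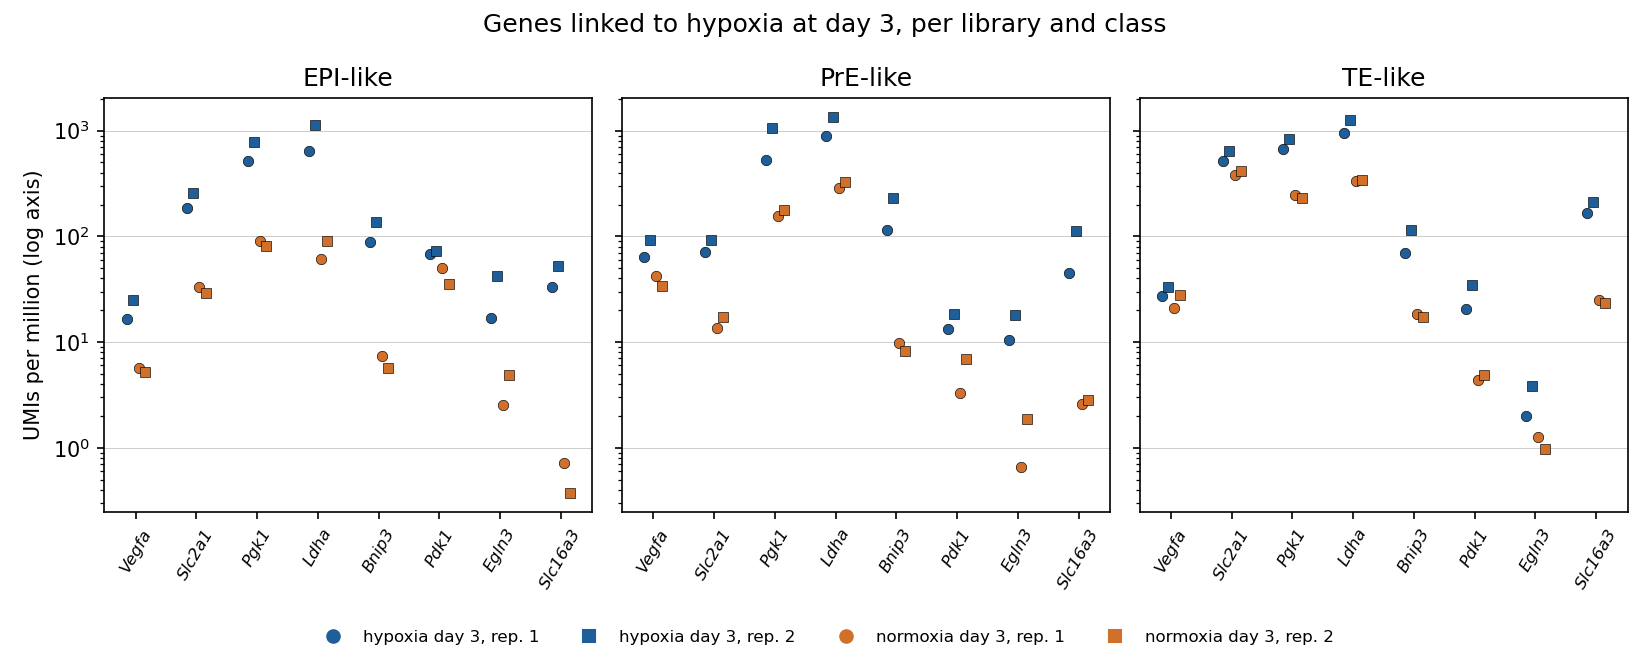
Expression (CPM, log axis) of named hypoxia-response genes in EPI-like, PrE-like and TE-like cells, with 1 point per day-3 library (blue for hypoxia, orange for normoxia). Slc16a3 lies higher in both hypoxia libraries than in both normoxia libraries in each of the 3 classes.

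The oxygen effect itself was compared between classes. Of 13849 genes tested with edgeR's interaction term, the effect differed between TE-like and EPI-like cells for 54 genes, 12 more positive and 42 more negative in TE-like cells. It differed between PrE-like and EPI-like cells for 10 genes (2 and 8) and between TE-like and PrE-like cells for 11 (4 and 7). At an unadjusted p under 0.05 there were 1208, 903 and 921 genes. Of the HIF targets and glycolytic enzymes, 13 differed between TE-like and EPI-like cells, with a smaller effect in TE-like cells for 12 of them, such as Ldha and Slc2a1, and a larger one for Pdk1. For TE-like against EPI-like cells the count was 262 without hypoxia replicate 1, 8 and 14 without normoxia replicate 1 or 2, and 13 with all sums thinned to the same depth. For PrE-like against EPI-like cells it was 63 and 23 without hypoxia replicate 1 or 2 and 0 and 5 without normoxia replicate 1 or 2, and for TE-like against PrE-like cells 91 and 35 without hypoxia replicate 1 or 2, 2 without normoxia replicate 2 and 5 after thinning.

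The comparison of day 3 with day 2 under hypoxia asked how the blastoids changed in culture. Over all cells edgeR called 0 of 16270 genes, with 2094 at an unadjusted p under 0.05, and DESeq2 called 374. The genes with the smallest p were Fads2, a fatty acid desaturase (2.58), Fabp5, a fatty acid carrier (2.01), Crebrf (-2.02), Nat8l (-1.56) and Eras (-1.66), each at an edgeR adjusted p of 0.0999. Camera called 14 of 34 lists, 11 higher and 3 lower, and none with an estimated correlation. Without normoxia replicate 1 the count was 263 and without normoxia replicate 2 it was 283. The comparisons by class that follow were added after the data had been seen, and the single day-2 library was assumed to vary like the others. With 1 library at day 2, an effect of day cannot be told apart from traits of that library.

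In EPI-like cells, most listed targets of Wnt signalling and some genes of early mesoderm were higher at day 3. Of 11 Wnt targets 7 rose (8 adjusted over the list alone). Sp5, a direct Wnt target (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729, plus strand), went from 3.16 CPM to 49.1 ± 6.93 CPM (SD, n = 2; log2 fold change 3.96, SE 0.35, edgeR adjusted p = 0.000775). Cdx1 rose by 3.36 (SE 0.27), Axin2 by 2.05 (SE 0.22, edgeR adjusted p = 0.0013) and Notum by 2.17. Of 8 mesoderm and primitive streak genes 3 rose and 1 fell (5 rose and 1 fell adjusted over the list alone), and Nodal fell by 0.93. Both lists hold Cdx1 and T, and each had a camera adjusted p of 0.48 with an estimated correlation. T, the brachyury gene, had 3.34 ± 0.659 CPM at day 3 and 0.135 CPM at day 2, the latter from 2 UMIs.

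Some trophectoderm-associated genes rose in EPI-like cells too. Of 19 core trophectoderm markers 5 rose and 1 fell (8 rose and 2 fell adjusted over the list alone, adjusted p = 0.516 with an estimated correlation). Gata2 rose by 3.67 (SE 0.40, edgeR adjusted p = 0.00138), Cdx2 from 0.875 to 8.71 ± 0.337 CPM (3.30, SE 0.52, edgeR adjusted p = 0.00844), Tfap2c by 2.49 (SE 0.46, edgeR adjusted p = 0.0166) and Fabp3 by 1.61 (SE 0.18, edgeR adjusted p = 0.00158). Of 11 trophoblast differentiation genes 4 rose (5 rose and 2 fell adjusted over the list alone), and of 20 genes of blastocoel formation 3 rose (4 adjusted over the list alone), among them the water channel Aqp3 (1.62). Of 16 BMP and TGF-beta targets 5 rose and 1 fell (6 and 2 adjusted over the list alone), with Msx2 at 2.58, Id3 at 1.27 and Id1 at 1.02. These 3 lists had an adjusted p of 0.516 with an estimated correlation.

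Genes of the integrated stress response, which is run by the transcription factor Atf4, fell in EPI-like cells, 7 of 19 (14 adjusted over the list alone). Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381, plus strand) fell from 100.2 to 25.9 CPM (-1.95, SE 0.17, edgeR adjusted p = 0.000775), Trib3 by 1.71 (SE 0.16, edgeR adjusted p = 0.000838) and Atf4 by 0.81 (SE 0.13, edgeR adjusted p = 0.00981). Of 10 genes of DNA methylation 2 fell (5 adjusted over the list alone), among them Dnmt3l (-1.57, SE 0.13, edgeR adjusted p = 0.000775). Of 22 G2 and M phase genes 6 fell (13 adjusted over the list alone), such as Nusap1 (-0.82). These 3 lists had an adjusted p of 0.48 with an estimated correlation. The pluripotency-linked genes Utf1 (-1.33) and Eras (-2.07, SE 0.20, edgeR adjusted p = 0.000838) fell, whereas Pou5f1 (-0.42, adjusted p = 0.11) and Nanog (-0.13, adjusted p = 0.725) did not pass the test.

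HIF targets (9 of 35 rose and 1 fell, 17 and 2 adjusted over the list alone), glycolysis (3 of 16 rose, 6 adjusted over the list alone) and cholesterol synthesis (4 of 21 rose, 10 adjusted over the list alone) were called higher in EPI-like cells at day 3, each at an adjusted p of 0.516 with an estimated correlation. Ldha rose by 1.32 (SE 0.31, edgeR adjusted p = 0.0377), Bnip3 by 0.99 and Hmgcr, the rate-limiting enzyme of cholesterol synthesis, by 1.57. In all, 319 genes rose and 306 fell of 13694, with 2621 at an unadjusted p under 0.05, and camera called 19 of 32 lists, 14 higher and 5 lower. Those not yet given were, on the higher side, mitochondrial transcripts (1 of 13 rose), ribosomal proteins (none of 28), NRF2 targets of the oxidative stress response (1 of 21 rose and 1 fell), polar trophectoderm (3 of 18 rose) and lysosome genes (2 of 18 rose). On the lower side were S phase (1 of 20 fell) and formative pluripotency genes (2 of 18 fell). Adjusted over the list alone these counts were 2, 0, 4 and 2, 4 (with 2 lower), 8, 4 and 5, and their adjusted p lay between 0.48 and 0.558 with an estimated correlation. Most day-2 cells lay in cluster 2 and most hypoxia day-3 cells in cluster 7. The count was 1601 without hypoxia replicate 1, 1075 without hypoxia replicate 2, 342 with sums thinned to the same depth and 107 with each library clustered by itself.

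In PrE-like cells, Cubn and Lrp2, which encode endocytic receptors, and Dab2, which encodes their adaptor, fell by day 3. Cubn (ENSMUSG00000026726, chromosome 2, 13276338 to 13491813, minus strand) went from 404 CPM to 28.2 ± 20.0 CPM (SD, n = 2; log2 fold change -3.98, SE 0.53, edgeR adjusted p = 0.0276), Dab2 fell by 2.94 (SE 0.31, edgeR adjusted p = 0.0128) and Lrp2 by 2.08 (SE 0.27, edgeR adjusted p = 0.0276). Of 15 PrE markers 3 fell (1 rose and 6 fell adjusted over the list alone). Of 9 visceral endoderm genes 2 fell (1 rose and 5 fell adjusted over the list alone). These were Cubn and Lrp2, which both lists hold, so the counts overlap. Of 15 parietal endoderm genes 1 fell (6 adjusted over the list alone). Each list had a camera adjusted p of 0.357 with an estimated correlation. Lefty2 rose from 2.03 to 84.4 ± 59.5 CPM (5.40, SE 0.80, edgeR adjusted p = 0.0491), and Sox17 (0.50) and Gata6 (0.28) did not pass the test. The test called 14 of 10729 genes, 4 higher and 10 lower, with 1153 at an unadjusted p under 0.05, and camera called 17 of 30 lists. Of those not yet given only 1 gene, a BMP and TGF-beta target, rose over all genes tested (6 of 14 adjusted over the list alone), while 14 of 33 HIF targets rose and 1 fell and 8 of 15 glycolytic enzymes rose adjusted over the list alone. The adjusted p of these lists lay between 0.357 and 0.659 with an estimated correlation. Day-2 cells came mostly from cluster 10 and day-3 cells mostly from cluster 14. The count was 533 without hypoxia replicate 1, 30 without hypoxia replicate 2 and 24 without normoxia replicate 2, and 7 at the lower clustering resolution.

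In TE-like cells, cholesterol synthesis was higher at day 3, with 19 of 21 genes called (20 adjusted over the list alone). Nsdhl rose by 1.33 (SE 0.13, edgeR adjusted p = 0.000265), Dhcr7 and Idi1 by 1.41 each and Cyp51 by 1.26. Single genes that rose were Fads2 (ENSMUSG00000024665, chromosome 19, 10062765 to 10101746, minus strand; 2.62, SE 0.18, edgeR adjusted p = 3.9e-05), Fabp5 (1.79), Scd2 (1.41) and Acsl4 (1.52). Of 21 NRF2 targets 9 rose (15 adjusted over the list alone), and of 16 glycolytic enzymes 10 rose (12 adjusted over the list alone). Of 19 genes of the integrated stress response 7 fell (11 adjusted over the list alone), among them Chac1 (-1.53) and Trib3 (-1.40). These 4 lists had an adjusted p of 0.767 with an estimated correlation.

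Trophoblast differentiation genes moved both ways in TE-like cells. Of 15 on the list 4 rose and 1 fell (7 and 3 adjusted over the list alone), with Gcm1, a driver of labyrinth trophoblast, at 3.50 (SE 0.33, edgeR adjusted p = 0.000181), Flt1 at 1.29 and Ascl2 at -0.82. Of 13 mitochondrial transcripts 2 rose (8 adjusted over the list alone). Both lists had an adjusted p of 0.767 with an estimated correlation. HIF targets (10 of 36 rose, 18 rose and 4 fell adjusted over the list alone), Wnt targets (3 of 11 rose, 5 adjusted over the list alone) and S phase genes (5 of 20 rose, 7 adjusted over the list alone) had an adjusted p of 0.84 with an estimated correlation, as had oxidative phosphorylation (1 of 48 rose, 0 adjusted over the list alone), ribosomal proteins (0 of 28) and p53 targets (2 of 19 rose and 1 fell, 2 and 1 adjusted over the list alone). Lgr5 and Axin2, both Wnt targets, rose by 3.21 and 2.20. Crebrf (-2.45, SE 0.16, edgeR adjusted p = 3.9e-05), Pdcd4 (-2.12) and Krt8 (-0.61) fell. Of 14754 genes, 388 rose and 490 fell, with 3299 at an unadjusted p under 0.05, and camera called 12 of 32 lists. Cluster 3 held 650 of the 881 TE-like cells at day 2, but 64 of 1220 and 70 of 2157 in hypoxia day-3 replicates 1 and 2. DESeq2 split its calls into 464 higher and 343 lower. The count was 2362 without normoxia replicate 1 and 2713 without normoxia replicate 2, against 589 without hypoxia replicate 2.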

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

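All tests of explanations in this part were chosen only after the results had been seen, except the test of X-linked transcripts in cluster 13, which was written before.

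The effect of hypoxia differed between classes by the interaction term for 54 genes between TE-like and EPI-like cells, 10 between PrE-like and EPI-like cells and 11 between TE-like and PrE-like cells. All values that follow are differences of log2 fold changes, with the first-named class minus the other, and have an edgeR adjusted p of at most 0.049. TE-like minus EPI-like differences were negative for Igfbp2 (-3.45), Slc16a3 (-3.07), Anxa2 (-2.998), Slc2a1 (-2.25), Ldha (-1.89), Prelid2 (-1.73), Bnip3 (-1.71), Skil (-1.69), Pfkl (-1.66), Vegfa (-1.51), Pgk1 (-1.24) and Pkm (-0.69). They were positive for Pdk1 (1.84), Bmp4 (1.26), Cald1 (1.23) and Egr1 (1.09). PrE-like minus EPI-like differences were -2.14 for Prelid2, -1.71 for Ldha, -1.56 for Pfkl, -1.18 for Upp1 and 1.91 for Klhl2. TE-like minus PrE-like differences were -1.91 for Bnip3, -1.86 for Klhl2, -1.83 for Slc2a1, 1.30 for Egr1, 1.60 for Sox2 and 2.24 for Bmp4. For Ndufa4l2 the fitted differences were -7.07 (TE-like minus EPI-like) and -6.40 (TE-like minus PrE-like), of which the former rests on 3 UMIs in normoxic EPI-like cells, and neither is a measure of size.

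Among the HIF targets and glycolytic enzymes, the effect was smaller in TE-like than in EPI-like cells for 12 and larger for 1. After all sums had been thinned to the same depth, the median difference of the 12 genes was -1.80, against -1.69 before. Thinning draws from the same counts and leaves the expected difference nearly unchanged. It therefore cannot decide whether a difference in depth between the classes plays a part. Thinning ended the calls of some of them as their errors grew, as for Bnip3 (from -1.71, SE 0.19, to -1.27, SE 0.39) and Slc16a3 (from -3.07, SE 0.44, to -2.24, SE 0.68), but not those of Ldha (-1.81, SE 0.17) or Slc2a1 (-2.03, SE 0.21). RNA of other classes in the droplets and a biological difference between the classes were not tested and stay open. Without either normoxia replicate, most of the 54 genes that differed between TE-like and EPI-like cells lost their call. Some of the genes called in those fits were not among the 54. Without hypoxia replicate 1 more genes were called.

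Y-linked transcripts, which no comparison used, were seen in 71.4% of the 297 cells of cluster 13 (95% Clopper-Pearson interval 65.9 to 76.5), with 80.0% at day 2, 73.9% and 29.4% in hypoxia day-3 replicates 1 and 2, and 66.4% and 90.5% in normoxia replicates 1 and 2, against 1.01% of EPI-like, 0.475% of PrE-like and 0.25% of TE-like cells. The cluster, whose share of kept cells was 4.29% at day 2, 2.80% and 0.451% in the hypoxia day-3 replicates, and 6.52% and 0.551% under normoxia, scored 0.673 for EPI markers and 0.679 for germ cell markers, with 0 EPI markers and 1 marker of another type among its top 10 genes. The test of doublets gave a median of UMIs per cell 1.19 to 1.43 times that of EPI-like cells. This lay under the limit set for doublets in all libraries, but above the EPI-like median in each. As that limit was chosen after the results had been seen, the test cannot exclude doublets, which stay open. For free RNA, Y-linked genes were left out of the variable genes and the cluster highest in germ cell markers was taken (291 cells, 283 of them from cluster 13). It had Y-linked UMIs in 64.0% to 80.0% of its cells in 4 libraries, against 0.149% to 0.889% of EPI-like cells. In hypoxia day-3 replicate 2 the share was 0 of 12 cells, against 2.65%, so that the lowest ratio was 0 and the test could not decide. In the other 4 libraries Y-linked UMIs were at 96.5 to 173 CPM in cluster 13. They were at 0 to 0.347 CPM in TE-like cells there, whose droplets free RNA would also reach. These values argue against free RNA in those 4 libraries, and it stays open in hypoxia day-3 replicate 2. That the cluster is XY cells beside EPI-like cells with 2 active X chromosomes was argued against: X-linked genes took a median of 1.78 times the share of UMIs they took in EPI-like cells (1.11 in normoxia replicate 2), where fewer were predicted, and no biological explanation was tested further.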

How the results depend on the processing

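The alternatives for day within classes, for cluster 13, for the thinned interaction, for TE-like against PrE-like cells, for class shares with a library left out and for clustering without Y-linked genes were chosen only after the data had been seen. Under the other clusterings and cell filters the difference in shares was 7.55 to 10.5 percentage points for EPI-like (12.4 reported), 2.55 to 4.79 for PrE-like (4.06) and -14.8 to -10.6 for TE-like cells (-14.7), and none of these differences had a call to lose. The EPI-like share of normoxia replicate 2 (5.98%) was 10.2% in cells with at least 2000 genes and under 10% mitochondrial UMIs, and 12.0% with each library clustered by itself, where 202 of its 457 cells named EPI-like formed a cluster with a median of 3101.5 UMIs, collagen genes and 0 EPI markers among its top 10 genes. Without Y-linked genes among the variable genes the share of Y-positive cells in the matching cluster was 68.4% (71.4% reported). Counts of genes passed 1.5 times the reported value, up or down, under the settings below; where not stated otherwise the cause was not tested.

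DESeq2's test called 253 genes (2 reported) for oxygen in all cells, 192 (111) in EPI-like and 40 (13) in PrE-like cells, and for day 374 (0) in all, 400 (625) in EPI-like and 28 (14) in PrE-like cells. Its size factors in edgeR left 1 for oxygen in all cells. Without a filter on low counts the calls for oxygen were 115, 893, 167 and 1130 in all, EPI-like, PrE-like and TE-like cells, and for day 154, 1331, 418 and 1733. Keeping doublets gave 71 for oxygen in EPI-like and 9 for day in PrE-like cells. Cells with at least 2000 genes and under 10% mitochondrial UMIs gave 171 for oxygen in EPI-like cells. Clustering each library by itself gave 34 for oxygen in EPI-like cells, and for day 107 in EPI-like and 7 in PrE-like cells; a resolution of 0.5 also gave 7 in the latter. With each library clustered by itself the EPI-like sum of normoxia replicate 2 held the cluster with collagen genes. Clusters like cluster 13 were named EPI-like in 4 of the libraries and in the other clusterings of all libraries, so these counts do not measure the clustering alone. Thinning gave 342 for day in EPI-like cells, and for the interaction 13 (54) for TE-like against EPI-like and 5 (11) for TE-like against PrE-like cells, with fewer UMIs as its construction sets.

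The replicate block, which pairs libraries by their number, gave 895, 1112, 401 and 1300 genes for oxygen in all, EPI-like, PrE-like and TE-like cells. The labels give no batch that would justify this pairing. The correlation of the deviations of replicates from their group means was 0.576, 0.275, 0.449 and 0.219. Libraries of the same number thus deviated partly in the same way in both oxygen groups. What they share was not tested.

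Leaving out each day-3 library in turn gave 3 to 267 genes for oxygen in all cells, 44 to 1509 in EPI-like, 0 to 193 in PrE-like and 126 to 1619 in TE-like cells. For day it gave 0 to 283 in all, 760 to 1601 in EPI-like, 10 to 533 in PrE-like and 589 to 2713 in TE-like cells. For the interaction it gave 8 to 262 for TE-like against EPI-like, 0 to 63 for PrE-like against EPI-like and 2 to 91 for TE-like against PrE-like cells. The shares differed by -4.56 to 29.4 points (EPI-like), -0.139 to 8.25 (PrE-like) and -33.5 to 4.04 (TE-like). A lone library left in a group was assumed to vary like the others. A change of sign was counted as a reversal only for named genes called in the reported fit or under the alternative. The only gene so counted was Sox17 for oxygen in TE-like cells, at -0.41 and not called in the reported fit. It ranged from -1.30 without normoxia replicate 1 to 2.18 without normoxia replicate 2.

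Lists called by camera fell from 19, 15, 17 and 11 for oxygen (all, EPI-like, PrE-like and TE-like cells) and 14, 19, 17 and 12 for day to 0 in each with an estimated correlation. Fry called 0, 1, 0 and 1 for oxygen and 0, 1, 0 and 0 for day. With a library left out, camera called 16 to 23, 9 to 20, 17 to 21 and 13 to 19 lists for oxygen and 16 to 17, 18 to 21, 16 to 18 and 11 to 15 for day. The fit over all 5 libraries gave 2, 151, 16 and 310 genes for oxygen, and cluster 13 counted as EPI-like gave 109 for oxygen and 704 for day in EPI-like cells, all within 1.5 times of the reported counts. The gene lists kept among the variable genes were tried on class shares only. The smallest class sum, of PrE-like cells, held 1562780 UMIs, and thinning to it gave 14 genes for oxygen there (13 reported).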

Other observations

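All tests of explanations in this part were chosen only after the results had been seen.

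Xist, the RNA that coats the inactive X chromosome, was abundant in TE-like cells, at 754 to 1162 CPM in the 5 libraries, and had 12.96 to 17.9 CPM in EPI-like cells. It was seen in 87.7% to 97.2% of TE-like cells (median UMIs 5139.5 to 49042) and in 7.47% to 23.6% of EPI-like cells (median UMIs 8502.5 to 19940). In cluster 13 it had 15.3 to 27.4 CPM. X-linked genes other than Xist took 3.07% to 3.36% of the UMIs of TE-like cells and 2.66% to 2.91% of those of EPI-like cells.

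Cluster 16, which carried collagen and other fibroblast-like genes but was not named by the marker rule, held 78 cells. Its share was 0.107% at day 2, 0.284% and 1.06% in hypoxia day-3 replicates 1 and 2, and 0.949% and 0.341% in normoxia replicates 1 and 2. The 2-cell-like cells of cluster 15 were 0.107% of the kept cells at day 2 and 0.119% to 0.345% at day 3.

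Trophectoderm markers that rose in EPI-like cells from day 2 to day 3 might come from RNA or cells of the TE-like class in the EPI-like sums. This was argued against for the 5 markers called, but only for RNA with the average make-up of the TE-like class. In the day-3 hypoxia library nearest its limit, replicate 2, their median EPI-like level was 19.4% of the TE-like level. The TE-like gene scarcest in EPI-like cells there, Elf5 with 7 UMIs, allows such a share of at most 1.07%. This limit cannot bound RNA from TE-like cells that hold little Elf5, so that source stays open. A change within EPI-like cells stays open as a hypothesis, found and tested on the same data, and the single day-2 library limits it.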
